A study of Mus musculus with 6 samples.

How the data were processed

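Gene expression was measured in osteoblastic cells of male mice on 6 single-channel Affymetrix arrays, 4 from wild-type (WT) mice and 2 from mice lacking the Y1 receptor for neuropeptide Y (Y1KO). Per the labels' protocols, stromal cells from the bone marrow of the long bones of the hind leg were cultured for 7 days. The cells carried a green fluorescent reporter driven by a 3.6-kb piece of the rat type I collagen promoter. Fluorescent cells were sorted by flow cytometry and total RNA was labelled with biotin using a whole-transcript kit.

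The deposited table holds log2 expression values, 1 per probe set and array, for 28815 probe sets. RMA and limma are named in the submitters' processing notes, with no versions, settings or order. The genome build and the probe annotation that the authors used are not given in the sources used here. The sorted values of the arrays differed by 0.0199 on average and the array medians lay between 5.3 and 5.37, so the deposited log2 values had already been brought to nearly the same distribution. No further normalization was applied. An array has no read depth, and the number of arrays, 4 against 2, limits the precision. A difference of log2 values is a ratio on the array's scale, which understates changes of genes near the background.

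Probe sets were named from the platform annotation held by the public repository, which can be old. Of all probe sets, 21780 had exactly 1 gene symbol, 1605 had several and 5430 were not listed there. No gene was named from a probe set with several symbols or none. Of the probe sets with 1 symbol, 21689 matched the RefSeq gene table of the mouse assembly GRCm38.p6 by gene identifier, and 0 symbols needed an update. This table was used for names and for the order of genes along chromosomes, and none of its coordinates are printed, because the array annotation names no build. Where 998 genes had several probe sets, the probe set with the highest mean over all 6 arrays stood for the gene. This left 19935 genes.

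The samples, tests, gene lists, rule for named genes and alternatives described here were fixed before the data were examined, except where stated. Y1KO was compared with WT by a linear model with moderated variance (limma 3.58.1 in R 4.3.3, lmFit and eBayes without trend or robust options). All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 19935 genes, and a gene was called at a limma adjusted p under 0.05. Only genotype entered the model. The verbs rose and fell are used only for called genes and lists. Values are means ± SD of log2 expression, and differences are Y1KO minus WT on the log2 scale with the standard error (SE) of the model. The series' design counts 4 and 2 mice, but the labels do not say whether each array is 1 mouse or 1 culture, so p-values measure the spread between these arrays, which may in part be technical.

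For Npy1r, an exact permutation test over the 15 splits of the arrays into 4 and 2 was added. The 50 measured genes on each side of Npy1r were compared with all other placed genes by Fisher's exact test on the number with an unadjusted p under 0.01. For the shift of 29 gene lists, camera was used with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. Camera with an estimated correlation and fry were run beside it. Members of each list were also counted after adjustment over the list alone. The lists covered the osteoblast lineage, osteocytes, adipocytes, chondrocytes, marrow stromal progenitors, the neuropeptide Y system, the cAMP and immediate early response, the Wnt, BMP and TGF-beta, IGF and Notch pathways, extracellular matrix, cell cycle, interferon response, inflammatory cytokines, oxidative phosphorylation, glycolysis and hypoxia, endoplasmic reticulum (ER) and amino acid stress, cholesterol synthesis and ribosomal proteins. Markers of other cells that the sort could hold were macrophages, osteoclasts, granulocytes, lymphocytes, erythroid cells and megakaryocytes, endothelium, smooth muscle and pericytes, skeletal muscle, and neural cells. List genes without a single-symbol probe set were not analysed here.

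Named genes were the 12 with the largest increase and the 12 with the largest decrease among called genes whose Y1KO arrays both lay beyond all WT arrays, leaving out predicted genes and families with uncertain probe sets. To these were added the neuropeptide Y receptors and ligands, Col1a1, the 4 members of smallest p from the osteoblast list and from each called list, the 2 members of smallest p from each list of other cells, and genes within 5 places of Npy1r with an unadjusted p under 0.01. Genes named outside this rule are marked as chosen after their values were seen.

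The alternatives were quantile normalization, centring of each array on its median, filters at the 40th and 60th percentile of mean expression, the mean of a gene's probe sets, all probe sets as units, eBayes with trend and robust options, array weights, the model without moderation (with camera run on its gene statistics for the lists), the replicate number as a block, a principal component of the residuals as a covariate, and each array left out in turn. With 1 Y1KO array left, the spread came from the WT arrays and the lone array was assumed to vary like them. Counts of list members without each array were added after the data were seen. The tests were checked on simulated data with the same 19935 genes and 4 and 2 arrays, in which 200 genes were changed. The model called 44.4% of genes changed by 0.5 log2 units and 100% of those changed by 1 or by 2, with 14 unchanged genes called and 0 called genes of the wrong sign. Camera called 0 lists when none was changed and 1 when 1 was lowered. The simulated noise used each gene's moderated variance and no differences shared by an array, so these shares may be higher than in the real data. In the real data Actn3, at -1.35, did not pass. The simulated genes varied independently, so this does not check the list test where genes of a list vary together. In the real data the estimated correlation was 0.43 for the cell cycle list.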

Results

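Expression was measured in sorted osteoblastic cells on 4 WT and 2 Y1KO arrays, and the comparison asks what the loss of the Y1 receptor changes in these cells. The array medians were 5.33, 5.32, 5.32 and 5.37 in WT replicates 1 to 4 and 5.3 and 5.32 in Y1KO replicates 1 and 2. Correlations over all genes, which are not independent replicates, were 0.9911 to 0.9958 among the WT arrays and 0.9961 between the Y1KO arrays, against 0.9762 to 0.9875 across genotypes. The first principal component held 63% of the variance and parted the genotypes. No 2 arrays were identical. The median SD per gene was 0.125 in WT and 0.078 in Y1KO.

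The transcript of the targeted gene, Npy1r, was near the bottom of the array's range in both genotypes. The Y1 receptor couples to inhibitory G proteins and lowers cAMP when neuropeptide Y binds. Npy1r stood at 2.94 ± 0.15 (SD, n = 4) in WT and 2.86 ± 0.04 (SD, n = 2) in Y1KO, at percentile 9.4 of all genes in WT. The WT arrays read 3.11, 2.84, 2.78 and 3, and the Y1KO arrays 2.89 and 2.83. The difference was -0.08 (SE 0.11, 95% interval -0.33 to 0.18, limma adjusted p = 0.768). An exact permutation test gave p = 0.6, where 15 splits allow none below 0.0667. A probe set this dim checks the genotype labels neither way, and the position of its probes relative to the deleted part is not given in the sources used here. The other receptors and ligands of the family were also not past the test, with differences of 0.14 for Npy2r, 0.16 for Npy4r, -0.08 for Npy5r, -0.03 for Npy6r, -0.12 for Npy, 0.16 for Pyy and -0.18 for Ppy. For Npy6r the sign turned to 0.03 with median-centred arrays. Among the 18 measured genes of the neuropeptide Y list, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.909). Col1a1, whose promoter drives the sorting reporter, stood at 13.42 ± 0.05 (SD, n = 4) in WT and 13.60 ± 0.03 (SD, n = 2) in Y1KO, a difference of 0.18 (SE 0.08, limma adjusted p = 0.225).

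The largest differences between genotypes were decreases in Y1KO. Esm1, a secreted proteoglycan, fell 17.8-fold, from 8.66 ± 0.73 (SD, n = 4) to 4.51 ± 0.28 (SD, n = 2). Il1rn, the interleukin-1 receptor antagonist, fell 15.7-fold, and Cxcl12, the chemokine that holds blood stem cells in the marrow, fell 11-fold from 11.3 ± 0.29 to 7.83 ± 0.11. Kitl, the ligand of the Kit receptor on blood progenitors, and Rspo2, an enhancer of Wnt signalling, fell 9.51-fold and 9.79-fold. The largest increases were smaller: Frzb, a secreted Wnt antagonist, rose 4.19-fold and Nt5e, an ectoenzyme that makes adenosine, rose 3.71-fold. Esm1, Il1rn, Kitl and Plpp3 in Y1KO (percentiles 31.8, 46.4, 44.2 and 40.7 of all genes) and Cdh10 and Scn3a in WT (11.9 and 25.5) lay below the median, where the array can understate a difference, so their folds and ranks are approximate.

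Of 19935 genes, 2541 passed the limma test (12.7%), 1217 higher and 1324 lower in Y1KO. Higher genes made up 47.9% of the calls, and 60.5% when each array was centred on its median. At least 2-fold changes were found for 189 higher and 292 lower genes, and at least 4-fold changes for 2 higher and 47 lower genes. In all 2541 called genes the Y1KO arrays lay beyond every WT array. Over all genes, 34.8% had groups that did not overlap, where chance gives 13.3%. The count rested on both Y1KO arrays: it was 944 without Y1KO replicate 1, 487 without Y1KO replicate 2, and 344 without moderation of the variance.

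**Figure D1:**
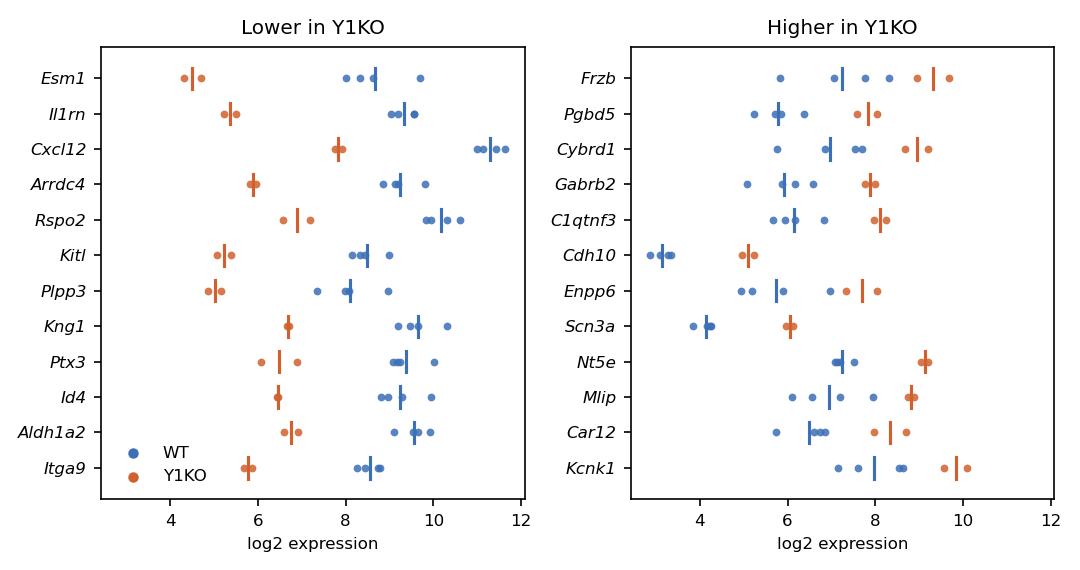
Expression of the 12 named genes with the largest decrease and the 12 with the largest increase in Y1KO, as log2 expression on the horizontal axis. Points are single arrays (4 WT, 2 Y1KO) and bars are group means; in each gene both Y1KO points lie beyond all WT points, with Esm1 at 8.66 in WT and 4.51 in Y1KO.

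The other genes with the largest decreases were Arrdc4, an arrestin-domain protein, at -3.34 (SE 0.22, limma adjusted p = 0.000171), Plpp3, a lipid phosphate phosphatase, at -3.07, Kng1, the kininogen gene, at -2.98, and Ptx3, a secreted pentraxin, at -2.89. Id4, an inhibitor of helix-loop-helix transcription factors, and Aldh1a2, which makes retinoic acid, each fell by 2.80, and the integrin subunit gene Itga9 fell by 2.78. For the 12 named decreases the limma adjusted p ran from 1.87e-05 for Il1rn to 0.00148 for Plpp3, and 0 of the 12 lost the call when any 1 array was left out. Without moderation 5 of the 12 lost it, Esm1, Plpp3, Kng1, Ptx3 and Id4. The other large increases were Pgbd5 at 2.02 (SE 0.27, limma adjusted p = 0.00234), the ferric reductase gene Cybrd1 at 1.97, the GABA receptor subunit gene Gabrb2 at 1.96, and the secreted protein gene C1qtnf3 and the cadherin gene Cdh10, both at 1.95. The phosphodiesterase gene Enpp6 rose by 1.95, the sodium channel gene Scn3a by 1.92, Mlip by 1.87, the carbonic anhydrase gene Car12 by 1.85 and the potassium channel gene Kcnk1 by 1.85. Their limma adjusted p ran from 0.000205 for Scn3a to 0.0485 for Frzb. Of the 12 named increases, 6 lost the call without Y1KO replicate 1, 8 without Y1KO replicate 2, 3 without WT replicate 1, 2 without WT replicate 4, 9 without moderation and 5 with trend and robust options. Frzb and Enpp6 lost it in each of these settings, and WT replicate 2 held the lowest value of each, 5.83 and 4.94. With quantile normalization and with all probe sets as units, Frzb lost it too.

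Cell cycle genes fell together in Y1KO. Of the 44 measured, 42 fell and 0 rose (43 and 0 adjusted over the list alone), with a median of -0.82 and a mean of -0.80 (camera adjusted p = 8.99e-35, adjusted p = 0.177 with an estimated correlation). Mcm4, a subunit of the helicase that opens DNA for replication, fell by 1.22, from 8.40 ± 0.07 (SD, n = 4) to 7.18 ± 0.12 (SD, n = 2). Mcm6 of the same helicase, Top2a, the topoisomerase of dividing cells, and the replication licensing gene Cdc6 fell by 1.22, 1.22 and 0.99. The 2 members that did not pass, named after their values were seen, were the G1 cyclins Ccne1 at -0.34 and Ccnd1 at 0.21. In WT the mean of the list over arrays, relative to the WT mean, lay between -0.07 and 0.06, and in the Y1KO arrays it was -0.70 and -0.90. The count of falling genes was 37 without Y1KO replicate 1 and 23 without Y1KO replicate 2. The mean of the macrophage list was 0.44 higher in Y1KO and that of the smooth muscle list -0.99 in the same arrays.

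Genes of marrow stromal progenitors and contractile genes of smooth muscle and pericytes also fell. Of 17 progenitor genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone), with a mean of -0.91 (camera adjusted p = 6.09e-06, adjusted p = 0.177 with an estimated correlation). Cxcl12 and Kitl fell the most, Pdgfrb, a growth factor receptor of perivascular cells, fell by 1.60 (SE 0.14, limma adjusted p = 0.000486), and Nt5e was the member that rose. Of 14 smooth muscle and pericyte genes, 11 fell and 0 rose (12 and 1 adjusted over the list alone), with a median of -1.23 and a mean of -0.99 (camera adjusted p = 4.94e-09, adjusted p = 0.203 with an estimated correlation). Actg2, a smooth muscle actin, fell by 1.93, the myosin light chain Myl9 by 1.60, the myosin kinase Mylk by 1.32 and the actin-binding Tagln by 1.13. Tagln lost its call without moderation. In WT, 13 of the 14 lay above the median of all genes, which does not show which cells made them. The progenitor and smooth muscle lists each share 3 genes with other lists. Without Y1KO replicate 1 or 2 the falling progenitor genes numbered 5 and 5, and the falling smooth muscle genes 6 and 5. The mean of the macrophage list moved the opposite way, by 0.44.

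**Figure D2:**
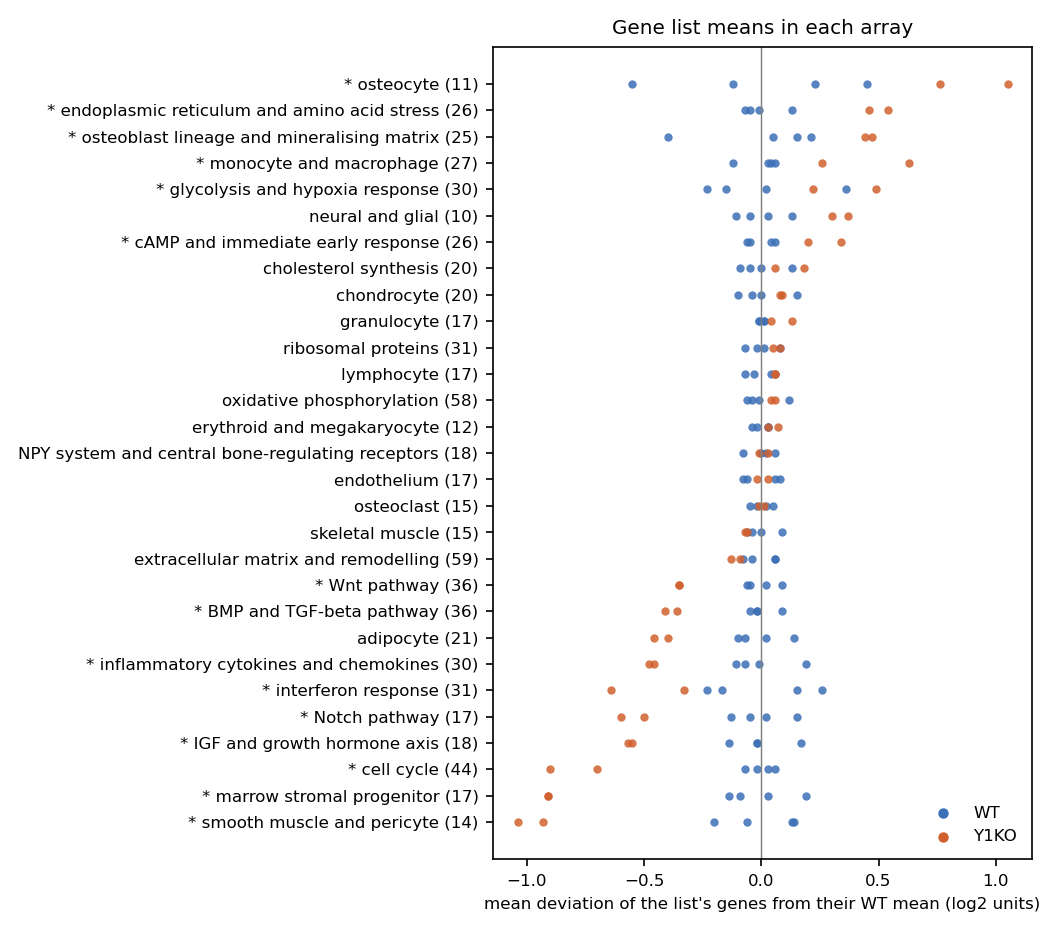
Mean log2 expression of the members of each gene list on each array, relative to the mean of the 4 WT arrays, with the number of measured genes in brackets and a star for camera adjusted p under 0.05. The cell cycle list lies at -0.70 and -0.90 in the Y1KO arrays and between -0.07 and 0.06 in WT, and the osteoblast list at 0.44 and 0.47 in Y1KO and between -0.40 and 0.21 in WT.

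Part of the osteoblast and osteocyte genes rose in Y1KO, while Col1a1 was not past the test. Of 25 osteoblast genes measured, 8 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.33 and a mean of 0.46 (camera adjusted p = 0.000438, adjusted p = 0.419 with an estimated correlation). Cthrc1, a secreted collagen repeat protein, rose by 1.13 (SE 0.23, limma adjusted p = 0.0129), the citrate transporter gene Slc13a5 by 0.98 and the collagen gene Col22a1 by 0.79. Named after their values were seen, Ifitm5, a membrane protein gene of mineralising osteoblasts, rose by 1.66, the homeobox gene Dlx3 by 1.27 and Smpd3, a sphingomyelinase needed for mineralisation, by 1.20. Mmp13, a collagenase, went the other way and fell by 2.19, from 11.71 ± 0.27 (SD, n = 4) to 9.52 ± 0.25 (SD, n = 2). Of 11 osteocyte genes, 3 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 0.00341, adjusted p = 0.318 with an estimated correlation). Pdpn, which marks early osteocytes, rose by 1.76 (SE 0.19, limma adjusted p = 0.00111), Fam20c, a kinase of secreted bone proteins, by 1.05 and the homeobox gene Irx5 by 0.88, while the matrix gene Tnc fell by 0.63. Pdpn, Fam20c, Irx5 and Tnc lost their calls without moderation, as did Cthrc1, Slc13a5 and Col22a1. The osteoblast count of rising genes was 0 without either Y1KO array and that of falling genes 2 without WT replicate 2, and the osteocyte count was 6 without WT replicate 2 or WT replicate 3 and 2 without Y1KO replicate 2, where 0 fell. By fry neither list was called, with adjusted p = 0.146 for osteoblast and 0.0523 for osteocyte genes. The macrophage mean was 0.44 higher in the same arrays, and higher in Y1KO replicate 2 (0.63) than in replicate 1 (0.26), and the smooth muscle mean changed by -0.99.

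Signalling genes moved unevenly, with several ligands, antagonists and binding proteins falling by large amounts. In the Wnt list 10 of 36 genes fell and 2 rose (13 and 5 adjusted over the list alone), with a median of -0.05 and a mean of -0.35 (camera adjusted p = 0.0287, adjusted p = 0.241 with an estimated correlation). The members that fell most act in different directions on the pathway: Rspo2 and Rspo3, which enhance Wnt signals, fell by 3.29 and 2.55, and Sfrp1, a secreted Wnt antagonist, fell by 2.52. Ccn5, a matricellular gene, fell by 1.99. In the BMP and TGF-beta list 12 of 36 genes fell and 4 rose (13 and 6 adjusted over the list alone), with a mean of -0.39 (camera adjusted p = 0.00232, adjusted p = 0.177 with an estimated correlation). Id4 fell by 2.80, the co-receptor gene Tgfbr3 by 2.41, the matrix protein gene Ltbp2 by 2.36 and the activin antagonist gene Fst by 1.58.

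In the IGF list 7 of 18 genes fell and 1 rose (7 and 2 adjusted over the list alone), with a mean of -0.56 (camera adjusted p = 0.0124, adjusted p = 0.234 with an estimated correlation). Igfbp4 fell by 2.41, from 11.6 ± 0.12 (SD, n = 4) to 9.19 ± 0.08 (SD, n = 2), and the binding proteins Igfbp5 and Igfbp7 fell by 2.71 and 1.33, while the stanniocalcin gene Stc2 rose by 1.20. In the Notch list 6 of 17 genes fell and 1 rose (9 and 1 adjusted over the list alone), with a mean of -0.55 (camera adjusted p = 0.000512, adjusted p = 0.177 with an estimated correlation). The glycosyltransferase gene Lfng fell by 1.75, the ligand gene Jag1 by 1.54, the receptor gene Notch1 by 1.24 and the coactivator gene Maml2 by 0.90. Of the named signalling genes, Rspo3, Ccn5, Id4, Igfbp5, Stc2, Jag1, Notch1 and Maml2 lost their calls without moderation. Without Y1KO replicate 1 or 2 the falling genes numbered 7 and 5 of the Wnt, 7 and 7 of the BMP and TGF-beta, 3 and 3 of the IGF and 3 and 3 of the Notch list. Without either Y1KO array 0 genes rose in the Wnt, BMP and TGF-beta and Notch lists, and the rising Wnt genes numbered 4 without WT replicate 1 or WT replicate 3 and 1 without WT replicate 4. The Wnt list lost its call without WT replicate 1 (adjusted p = 0.0822) or Y1KO replicate 1 (0.0538) and with the filters at the 40th (0.0754) and 60th percentile (0.056), and without moderation the Wnt and IGF lists had adjusted p of 0.0784 and 0.0626. The IGF mean was -0.89 with the filter at the 60th percentile. In the same Y1KO arrays the mean of the macrophage list was 0.44 higher and that of the smooth muscle list changed by -0.99.

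Genes of ER and amino acid stress and of the immediate early response rose in Y1KO. Of 26 stress genes, 15 rose and 0 fell (18 and 0 adjusted over the list alone), with a mean of 0.50 (camera adjusted p = 3.11e-09, adjusted p = 0.177 with an estimated correlation). Slc7a11, the cystine transporter gene, rose by 1.37 (SE 0.27, limma adjusted p = 0.0114), the ER chaperone partner gene Dnajb9 by 0.91, the transcription factor gene Xbp1 by 0.60 and Herpud1, which acts in ER-associated degradation, by 0.53. Of 26 genes of the cAMP and immediate early list, 8 rose and 1 fell (11 and 1 adjusted over the list alone), with a mean of 0.27 (camera adjusted p = 0.000796, adjusted p = 0.253 with an estimated correlation). Atf3, a stress-induced transcription factor gene, rose by 1.82, from 6.67 ± 0.33 (SD, n = 4) to 8.48 ± 0.01 (SD, n = 2), the immediate early gene Ier3 by 1.00, the RNA-binding Zfp36 by 0.63 and Fos by 0.48. Of 30 genes of glycolysis and hypoxia, 2 rose and 1 fell (4 and 1 adjusted over the list alone), with a mean of 0.35 (camera adjusted p = 0.000803, adjusted p = 0.58 with an estimated correlation). Car12 rose by 1.85 and the aldolase gene Aldoc by 1.25, the peptide gene Adm fell by 1.37, and the hexokinase gene Hk2 was 0.56 higher without passing the test. Without moderation Slc7a11, Dnajb9, Xbp1, Herpud1, Atf3, Ier3, Zfp36, Car12, Aldoc and Adm lost their calls. Aldoc and Adm also lost theirs with trend and robust options, and Aldoc and Fos with the replicate block. The stress count of rising genes was 0 without either Y1KO array and 9 without WT replicate 1. Without Y1KO replicate 1, Y1KO replicate 2 or WT replicate 1, 0 cAMP genes fell. The cAMP count of rising genes was 3 without Y1KO replicate 1 and 5 without Y1KO replicate 2, and the glycolysis count 5 without WT replicate 1, 1 without WT replicate 3 and 0 without Y1KO replicate 2, with 0 glycolysis genes falling without either Y1KO array. The glycolysis mean overlapped between genotypes, at 0.36 in WT replicate 1 and 0.22 in Y1KO replicate 1 relative to the WT mean, and fry did not call the list (adjusted p = 0.304). Without Y1KO replicate 2 the glycolysis mean was 0.22. The macrophage mean was 0.44 higher and the smooth muscle mean changed by -0.99 in the same arrays.

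Interferon-response genes and several inflammatory genes fell. Relative to the WT mean, the interferon list mean was -0.33 and -0.64 in Y1KO replicates 1 and 2. Among the WT arrays it lay between -0.23 and 0.26, close to Y1KO replicate 1. Of 31 interferon genes, 10 fell and 0 rose (13 and 0 adjusted over the list alone), with a mean of -0.48 (camera adjusted p = 5.47e-06, adjusted p = 0.358 with an estimated correlation). The immunoproteasome gene Psmb8 fell by 0.93 (SE 0.11, limma adjusted p = 0.00165), the ubiquitin ligase gene Herc6 by 0.98, Ifit2 by 0.92 and the transcription factor gene Stat2 by 0.79. Of 30 inflammatory genes, 4 fell and 2 rose (4 and 2 adjusted over the list alone), with a median of -0.09 and a mean of -0.47 (camera adjusted p = 0.0118, adjusted p = 0.234 with an estimated correlation). The members that fell were Il1rn, the chemokine gene Cxcl14 by 2.71, the haptoglobin gene Hp by 2.66, from 11.05 ± 0.12 (SD, n = 4) to 8.39 ± 0.15 (SD, n = 2), and Csf1, the macrophage growth factor gene, by 1.69. Without either Y1KO array the falling interferon genes numbered 2. The rising inflammatory genes numbered 1 without any 1 WT array or Y1KO replicate 1 and 0 without Y1KO replicate 2. Fry gave the interferon list an adjusted p of 0.116, and without moderation the inflammatory list had 0.0604. Psmb8, Stat2, Herc6, Ifit2, Csf1 and Cxcl14 lost their calls without moderation. The inflammatory mean was -0.97 and -1.43 with the filters at the 40th and 60th percentile, which leave out its dim members. The mean of the macrophage list was 0.44 higher and that of the smooth muscle list changed by -0.99 in the same arrays.

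**Figure D3:**
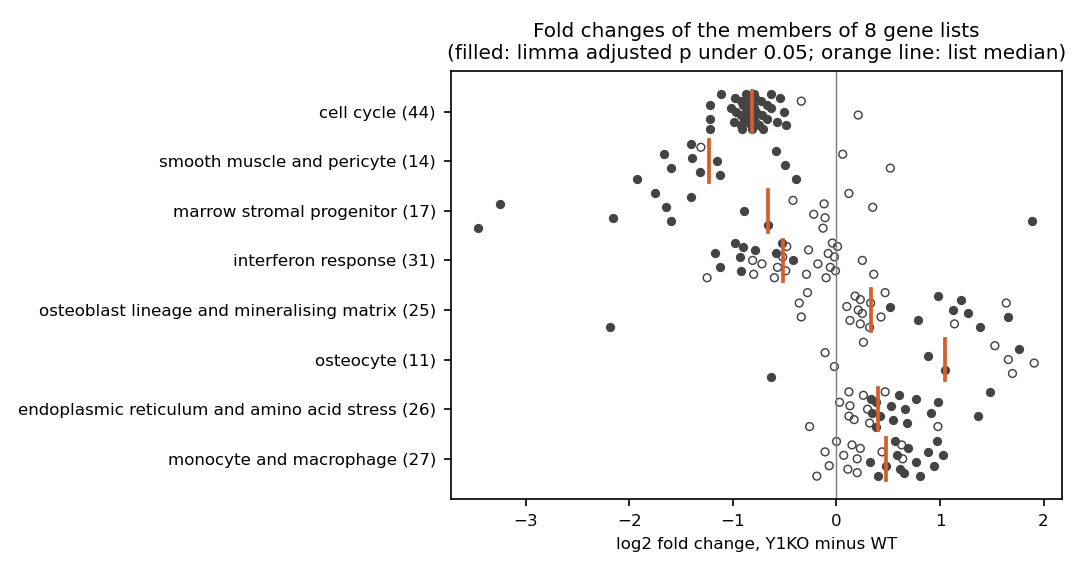
Log2 difference, Y1KO minus WT, of each measured member of 8 gene lists. Filled points passed the limma test, open points did not, and the orange line is the median of the list, which is -0.82 for cell cycle and 0.40 for ER and amino acid stress genes.

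Among markers of other cells, macrophage genes were the list that rose. Of 27, 14 rose and 0 fell (17 and 0 adjusted over the list alone), with a mean of 0.44 (camera adjusted p = 4.07e-08, adjusted p = 0.281 with an estimated correlation). The Fc receptor gene Fcgr3 rose by 1.03, the protease gene Ctss by 0.88 (SE 0.13, limma adjusted p = 0.0033), Adgre1, which codes for F4/80, by 0.81 and the complement gene C1qa by 0.58. Only 5 of the 27 lay above the median of all genes in WT. The count was 9 without WT replicate 1, 5 without WT replicate 4 and 1 without Y1KO replicate 2, where the mean was 0.26, and the list lost its call with the filter at the 60th percentile (adjusted p = 0.113). Of 15 osteoclast genes, 2 fell and 0 rose (2 and 1 adjusted over the list alone), the integrin gene Itgb3 by 1.00 and the proton pump gene Tcirg1 by 0.46 (camera adjusted p = 0.976). No granulocyte gene of 17 passed, with Ngp at 0.31 and Mpo at 0.30 (camera adjusted p = 0.251). Among 17 lymphocyte genes Cd4 rose by 0.37 and Vpreb1 stood at 0.29 (camera adjusted p = 0.345), and Cd4 lost its call with either Y1KO array or any WT array but replicate 3 left out. Cd4 also lost it with quantile normalization, all probe sets as units, the replicate block and no moderation. Of 12 erythroid and megakaryocyte genes and of 17 endothelial genes 0 passed, with Car1 at 0.32, Gp9 at -0.25, Sox18 at 0.23 and Sox17 at -0.16 (camera adjusted p = 0.435 and 0.939). Of 15 skeletal muscle genes 0 passed, with Actn3 at -1.35 and Des at 0.52 (camera adjusted p = 0.909). Among 10 neural genes 3 rose, the tubulin gene Tubb3 by 1.53, Nrcam by 0.59 and, chosen after its value was seen, Stmn2 by 1.47 (camera adjusted p = 0.164, and 0.0451 and 0.0469 with the filters at the 40th and 60th percentile). Each of the lymphocyte, granulocyte, erythroid, endothelial and skeletal muscle lists had 0 genes called after adjustment over the list alone, and the neural list had 4 higher and 1 lower. Without either Y1KO array 1 neural gene rose and 1 osteoclast gene fell, the latter also without WT replicate 1 or WT replicate 3, and without WT replicate 2 the skeletal muscle list had 1 gene higher and 1 lower. For the osteoclast and endothelial lists the median, the mean and the camera direction differed in sign. Fcgr3, Ctss, Adgre1, C1qa, Tcirg1, Tubb3 and Nrcam lost their calls without moderation.

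Adipocyte, chondrocyte, matrix and metabolic lists were not called as a whole in the planned main test, though single members changed. Of 21 adipocyte genes, 6 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.0817). Named after their values were seen, the lipoprotein lipase gene Lpl fell by 2.71, the fatty acid binding protein gene Fabp4 by 1.87 and Pparg, the main transcription factor of adipocytes, by 1.45, while the fatty acid transporter gene Cd36 rose by 0.94. Of 20 chondrocyte genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.345): Hapln1 rose by 1.34, Col11a2 by 1.28 and Sox6 by 0.45, and Col2a1 fell by 1.59 and Col10a1 by 0.70, all chosen after their values were seen. Of 59 matrix genes, 17 fell and 11 rose (21 and 16 adjusted over the list alone, camera adjusted p = 0.211). Of these, also chosen after their values were seen, the basement membrane collagen genes Col4a1 and Col4a2 fell by 1.40 and 1.56, and the proteoglycan gene Dcn rose by 1.52. In the cholesterol list 2 of 20 genes rose, Insig1 by 0.56 and Cyp51 by 0.40, both chosen after their values were seen (2 adjusted over the list alone, camera adjusted p = 0.0659). In the oxidative phosphorylation list 1 of 58 genes fell, Ndufs4 by 0.37, chosen after its value was seen (0 adjusted over the list alone, camera adjusted p = 0.203). Of 31 ribosomal protein genes 0 passed (0 adjusted over the list alone, camera adjusted p = 0.16). Other settings called some of these lists: adipocyte genes were lower by fry (adjusted p = 0.0121), with centred arrays (0.04) and without WT replicate 1 (0.0488) or WT replicate 2 (0.0242), and matrix genes lower with the replicate block (0.0137). Higher were cholesterol genes with trend and robust options (0.0495), array weights (0.0434) and without WT replicate 2 (0.00636) or Y1KO replicate 1 (0.0186), oxidative phosphorylation genes with the replicate block (0.0164) and without WT replicate 3 (0.00394), and ribosomal genes without WT replicate 3 (0.011).

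Without Y1KO replicate 1 the matrix counts were 7 lower and 5 higher and without Y1KO replicate 2 they were 6 and 2. Without WT replicate 4, 11 matrix genes fell. The adipocyte counts were 5 lower and 1 higher, and 4 and 0, without Y1KO replicates 1 and 2, the chondrocyte counts 2 lower and 1 higher, and 1 and 0, and the cholesterol counts 1 and 0 higher. Cholesterol genes also numbered 1 without WT replicate 1, WT replicate 3 or WT replicate 4, and the fall of Ndufs4 was the call that was lost without WT replicate 4 or either Y1KO array.

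Of the 29 lists, 15 were called, 6 higher and 9 lower. With an estimated correlation 0 were called, the lowest adjusted p being 0.177. Fry called 12, the adipocyte list among them.

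Genes next to Npy1r on chromosome 8 were compared with the rest of the genome because targeted mice can carry DNA of another strain around the locus. Of the 50 measured genes on each side, 18 of 100 (18%) had an unadjusted p under 0.01, against 2866 of 19749 other genes (14.5%), an odds ratio of 1.29 (95% interval 0.729 to 2.18, Fisher's exact test, p = 0.319). Those 18 changed in both directions, from the adipocyte list member Lpl at -2.71 to Psd3 at 0.92. Among genes within 5 places of Npy1r, Psd3 rose by 0.92 (SE 0.17, limma adjusted p = 0.00878), a call lost without moderation, and Npy5r was at -0.08. At an unadjusted p under 0.001 the shares were 13% and 6.9% and the odds ratio 2.02 (Fisher's exact test, p = 0.0265). Camera on the size of the change did not pass its threshold for the 100 neighbours. Psd3 lost its call without either Y1KO array.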

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

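All tests of explanations in this part were chosen after the results were seen. The rule for outlying arrays was fixed earlier.

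In 130 values checked for 1 WT array far from the other 3 (gap over range above Dixon's 95% critical value), 9 stood out, where chance at 1 in 20 gives 6.5. WT replicate 2 accounted for 5 of them. It read 10.79 for Csf1 (10.20 to 10.21 in the other WT arrays), 5.98 for C1qa (5.83 to 5.85), 11.31 for Tagln (10.88 to 10.95), 6.22 for Actn3 (7.63 to 7.73) and 7.43 for Psd3 (7.97 to 8.06). WT replicate 3 read 10.33 for Igfbp5 (9.14 to 9.21) and 8.44 for Psmb8 (8.29 to 8.31). WT replicate 1 read 2.18 for Npy6r (2.04 to 2.06), and WT replicate 4 read 9.89 for Herpud1 (9.72 to 9.75).

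Signal also appeared in data outside the comparison of genes. Of 7035 probe sets without a single gene name, 104 were higher and 157 lower in Y1KO by the same model over all probe sets.

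The first pattern is the number of called genes, 2541. Of the 15 splits of the 6 arrays into 4 and 2, only the real one (1) reached this count and the highest other had 0 calls. At an unadjusted p under 0.05 the real split had 4837 genes and the others at most 1715. Every other split mixes genotypes within a group, which widens its spread and lowers its calls whatever the cause of the real difference. In addition, 15 splits are too few for a share under 0.05. Chromosome 8, which holds Npy1r, had 5.2% of the called genes (95% interval 4.4 to 6.2) against 4.8% of all genes. It holds too few genes to carry most of the calls, so changes of its own genes alone are not the whole source. Of the named largest increases, Pgbd5, Enpp6 and Kcnk1 lie on chromosome 8, at 2.02, 1.95 and 1.85. The other named largest increases and all the named largest decreases lie elsewhere. Effects of strain DNA around the locus on genes elsewhere were not tested and stay open. Strain differences elsewhere, litter, and processing of the arrays by genotype stay open, as the labels give no batch or background strain. The genotype itself also stays open.

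The second pattern is the fall of cell cycle genes by 0.80 on average. If RNA of cells without osteoblast transcripts had diluted that of osteoblastic cells, the osteoblast list would have fallen alike. Its mean was instead 0.46 (95% interval over its genes 0.12 to 0.79) against -0.87 to -0.72 for the cell cycle list. These intervals take genes as independent and leave out the spread between arrays. Relative to the WT mean, the osteoblast mean was 0.44 and 0.47 in the Y1KO arrays and -0.40 to 0.21 in WT. The cell cycle mean was -0.70 and -0.90 in Y1KO and -0.07 to 0.06 in WT. A difference in maturation already present among WT cultures was tested by the slope of the cell cycle mean on the osteoblast mean over the WT arrays, which was -0.06 (95% interval -0.69 to 0.58), against a ratio of -1.75 between the mean cell cycle and mean osteoblast changes in Y1KO. The interval reached past that ratio without WT replicate 1 (-2.68 to 2.58) or WT replicate 2 (-9.11 to 9.92), so 4 WT arrays leave this explanation open. The dilution test concerns added RNA only. A different mix of cells within the sort was not tested and stays open. In the same arrays the progenitor mean was -0.91 and the smooth muscle mean -0.99 relative to WT. The genotype and a difference in plating density or culture timing also stay open, untested.

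The third pattern is the rise of macrophage genes, which the sort for the reporter should have removed. The mean of the 27 members was 0.26 in Y1KO replicate 1 and 0.63 in Y1KO replicate 2 relative to WT. Of the 5 most abundant, 4 (Lyz2, Ctss, Cd68 and C1qa) were above every WT array in both Y1KO arrays and Fcer1g (-0.11) was not, so carry-over of macrophages stays open, as does a coordinated change in the sorted cells themselves, which would give the same values. Carry-over of mixed blood cells of the marrow stays open too. The granulocyte mean was 0.08 (95% interval over its genes 0.00 to 0.16) against 0.30 to 0.58 for macrophage genes. These intervals take genes as independent and leave out the spread between arrays. In WT, 0 of the 17 granulocyte genes lay above the median of all genes, so changes near the background decide nothing.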

How the results depend on the processing

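The counts without each array of list members were chosen after the data were seen; all other alternatives were planned. The count of 2541 called genes (1217 higher, 1324 lower) lay between 2181 and 3163 under the other scalings, filters, units and models, except without moderation, which called 344 (140 higher, 204 lower), of which 313 were also called before. With each array left out in turn it ran from 487 to 2462 in total, the higher genes from 152 to 1172 and the lower from 335 to 1290, the lowest each time without Y1KO replicate 2, where 480 of the 487 were among the original calls. Fewer Y1KO arrays give wider errors by construction. Of the 100 named genes besides Npy1r, 53 lost a call without moderation, 31 without Y1KO replicate 2 and 23 without Y1KO replicate 1. The largest number under any other setting was 7, where named genes that a filter removed were not counted as lost. The only reversed signs among them were for Npy6r, which was never called, at 0.03 with centred arrays and -0.05 to 0.00 with arrays left out, the highest without WT replicate 1. Npy1r itself was never called, at -0.13 to -0.02 with arrays left out. With the replicate number as a block, 2181 genes (925 higher, 1256 lower) and 17 lists were called. The deviations of same-numbered arrays from their group means correlated at 0.01 and -0.20. The deviations of the 2 Y1KO arrays mirror each other, so this cannot tell whether the numbers pair the arrays.

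For lists, the value given is the mean log2 difference. With an estimated correlation 0 of 29 lists were called and the cause was not tested: osteoblast 0.46, osteocyte 0.91, progenitor -0.91, cAMP 0.27, Wnt -0.35, BMP and TGF-beta -0.39, IGF -0.56, Notch -0.55, cell cycle -0.80, interferon -0.48, inflammatory -0.47, glycolysis 0.35, ER stress 0.50, macrophage 0.44 and smooth muscle -0.99, means that the correlation cannot alter. Fry ended the calls of osteoblast (0.46), osteocyte (0.91), interferon (-0.48) and glycolysis genes (0.35), and no moderation those of Wnt (-0.35), IGF (-0.56) and inflammatory genes (-0.47). The Wnt call was also lost with the filters at the 40th (-0.39) and 60th percentile (-0.46), and when arrays were left out (-0.37 to -0.32; WT replicate 1 and Y1KO replicate 1), and the macrophage call with the filter at the 60th (0.58, adjusted p = 0.113), which leaves fewer genes. The filters at the 40th and 60th percentile moved the inflammatory mean to -0.97 and -1.43, and the filter at the 60th the IGF mean to -0.89. Calls were gained for adipocyte genes by fry (-0.43) and with centred arrays (-0.37), neural genes with the filters at the 40th (0.60) and 60th percentile (1.03), cholesterol genes with trend and robust options (0.12) and array weights (0.13), and matrix (-0.17) and oxidative phosphorylation genes (0.09) with the block. With 1 array left out, calls were gained for adipocyte (WT replicate 1 or 2), cholesterol (WT replicate 2 or Y1KO replicate 1), oxidative phosphorylation and ribosomal genes (both WT replicate 3). Uncalled lists whose test direction turned were osteoclast (0.00 by fry and without moderation, 0.01 quantile, 0.06 centred, -0.04 at the 60th percentile filter, -0.02 with weights, -0.04 with the block, -0.02 to 0.01 with arrays left out), granulocyte (-0.10 at the 40th), skeletal muscle (-0.04 with the block, -0.08 to -0.03 with arrays left out, the highest without WT replicate 4), endothelium (-0.02 to 0.03 with arrays left out) and neuropeptide Y genes (-0.01 to 0.03 with arrays left out). The neighbours of Npy1r had an odds ratio of 1.16 to 1.66 with other windows, and 2.02 at an unadjusted p under 0.001. Genes near the background, Npy1r among them, cannot show a loss on this array.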

Other observations

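The tests in this part were chosen after the results were seen. Genes were grouped by the shared stem of their symbols, which gave 303 families of at least 8 measured members, and 8 were called by camera with the preset correlation. With an estimated correlation 0 were called, the lowest adjusted p being 0.9997, so these families are descriptions.

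Of 28 genes whose symbols start with Sec, most of which code for parts of the ER translocon or of transport vesicles, 14 rose and 0 fell, with a median of 0.34 (camera adjusted p = 0.000191). Sec23a and Sec24d, which code for the inner coat of vesicles leaving the ER, rose by 0.77 and 0.68, the outer coat gene Sec31a by 0.57 and the translocon gene Sec61a1 by 0.52. In the same arrays the mean of the macrophage list was 0.44 higher and that of the smooth muscle list changed by -0.99. In addition, 7 of 20 nucleoporin genes (Nup) fell and 0 rose (camera adjusted p = 1.34e-05), 13 of 38 kinesin genes (Kif) fell and 2 rose (camera adjusted p = 0.000479), and 7 of 17 Rad genes, several of them for DNA repair, fell and 0 rose (camera adjusted p = 0.0187). The Mcm and Kif families overlap the cell cycle list, and 8 of 10 Mcm genes fell. The Parp, Cep and Slc families were called with 3 lower of 11, 5 lower of 37 and 62 higher against 12 lower of 364.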
